A study of Mus musculus with 15 samples.

How the data were processed

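Total RNA from glomeruli of male mice aged 12 weeks was labelled with biotin and hybridised to single-colour Affymetrix arrays, per the labels' protocols. The glomeruli had been isolated with magnetic beads, mincing, collagenase and sieving. There were 15 arrays in 4 groups, given by the strain and genotype labels: 3 from 129/SvEv wild-type mice, 4 from 129/SvEv mice carrying the renin transgene (RenTg) and the Ins2 Akita allele, 4 from C57BL/6 wild-type mice and 4 from C57BL/6 mice carrying both. Mice with both alleles are called mutants. The labels number the replicates without saying that each is a separate animal, so p-values measure the spread between these samples, which may be partly technical. Sample titles end in a further number that differs between samples. Its meaning is not given, and it entered no fit.

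The deposited values are log2 expression values, 1 per probe set and array, made with RMA and Partek 6.6 per the submitters' processing notes. Other steps before deposit are not given in the sources used here. The table held 22690 probe sets, and the array medians lay between 7.24 and 7.29. All columns of per-sample values were used. No pair of arrays was a duplicate: the closest pair shared 10 identical values, and the highest correlation between arrays was 0.996. For arrays, their number limits the precision, and no depth applies.

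Of the probe sets, 64 were controls, 20380 carried 1 gene symbol, 691 carried several and 1555 were unnamed here. Of those with 1 symbol, 20351 were matched by Entrez number to the gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. No genome build is given in the sources used here. Each gene was represented by its probe set with the highest mean over all arrays, which gave 12393 genes, 4956 of them with more than 1 probe set. Ren1, Ren2 and Ins1 were not analysed here, so the transgene itself was not measured. A further item is not reported here.

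The 4 group means were fitted to all 15 arrays together with lmFit, contrasts.fit and eBayes of limma 3.58.1 in R 4.3.3, without covariates. The strain average over genotypes was tested in a second limma fit, with strain and genotype as terms and no interaction. The 5 comparisons were the mutant effect in each strain, the difference of these effects, and the strain difference in wild-type and in mutant mice. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Of 28 gene lists, 12 held cell type markers (podocyte, mesangial cell and pericyte, glomerular endothelial cell, parietal epithelial cell, juxtaglomerular cell and renin-angiotensin genes, proximal tubule, distal nephron segments, macrophage and dendritic cell, lymphocyte, neutrophil, red blood cell, fibroblast). The other 16 held pathway genes. The lists held 601 genes, 530 of them measured. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Means of lists per array were compared between groups with exact permutation tests, and correlations across arrays with permutation tests (exact within a strain, 100000 resamples over all arrays) in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

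The named genes were fixed by a rule: up to 10 called genes per direction with the largest change and no overlap between groups, or, where fewer than 5 were called, the 5 with the smallest unadjusted p. Up to 4 members of each list with the smallest p and 16 genes of diabetic kidney disease were added. Genes called with the tubule covariate or in the averaged effect, and the most abundant genes of some lists, were named after their values were seen. The groups, tests, lists, this rule and the first set of alternatives were fixed before the data were examined. Those alternatives were other treatments of probe sets, filters on dim genes at a log2 value of 6 or the upper 50%, 3 further normalizations, other variance models, array weights, a fit of the compared groups alone, the replicate number as a block, the mean of the proximal tubule list as a covariate, stricter thresholds and leaving out each array. Others were chosen after seeing the data: leaving out arrays with the covariate in the fit, in list tests and in the correlation of effects, removing the arrays of highest and lowest tubule content in each C57BL/6 group, combining block and covariate, the covariate in the correlation of effects, and averaging the mutant effect over the strains.

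The steps were tested on simulated data with 12393 genes and independent noise. In each, 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. For the 129/SvEv mutant effect 43.3% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered. For the C57BL/6 effect the shares were 49.3%, 71.6% and 98.5%. With this many genes changed at once the adjusted threshold is looser than where few change. The shares are therefore not the power of the real comparisons. With the tubule covariate, 71.6% and 73.1% of the genes changed 1.5-fold were recovered in 129/SvEv and C57BL/6, with 7 and 11 false calls against 2 and 2 without it. The simulated values held each gene's fitted linear trend with that covariate, so better recovery with it was set in advance. These shares therefore do not show a gain in the real arrays.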

Results

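Glomerular transcripts were measured at 12 weeks of age in wild-type mice and in mice with diabetes and hypertension, on the 129/SvEv and the C57BL/6 background. Diabetes comes from the Akita allele of Ins2, a misfolding form of insulin, and hypertension from a renin transgene. The series title asks whether susceptibility to diabetic kidney disease is related to inflammation, so the difference between strains in the mutant effect is the comparison of most interest. Values are deposited log2 values, errors of log2 changes are standard errors (SE), and group sizes are 3 (129/SvEv wild type) or 4.

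Podocyte transcripts were abundant on every array: Podxl, the brightest gene of its list, which encodes a podocyte surface sialomucin, lay between 13.2 and 13.8. Tubule transcripts were present as well, in amounts that varied widely. Kap, an androgen-regulated gene of the proximal tubule, ranged from 10.1 to 13.8, and Slc27a2, a fatty acid transporter, from 8.43 to 13.3. The mean of the 19 proximal tubule genes ran from 7.05 on C57BL/6 wild-type replicate 1 to 12.0 on C57BL/6 wild-type replicate 3, a 31.0-fold range. Over all 15 arrays it correlated with the first principal component, which held 64.6% of the variance (r = 0.962, rho = 0.989, permutation p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 5e-05 over 5 relations).

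Arrays with more proximal tubule transcripts had lower podocyte means (r = -0.737, rho = -0.807, permutation p = 0.00198 and 0.00048, adjusted p = 0.00247; r = -0.733 without the 2 farthest arrays). The relation had the same sign within each strain (129/SvEv r = -0.655, exact p = 0.113; C57BL/6 r = -0.753, exact p = 0.0325). Mesangial (r = -0.831, adjusted permutation p = 0.0003) and endothelial markers (r = -0.663, adjusted permutation p = 0.00704) were also lower, and distal nephron markers were higher (r = 0.756, adjusted permutation p = 0.00167). The proximal tubule mean did not separate mutants from wild types (129/SvEv 9.67 ± 0.859 against 10.2 ± 0.997, exact permutation p = 0.571; C57BL/6 9.88 ± 1.93 against 9.92 ± 2.18, exact permutation p = 0.971; SD). Neither the labels nor the values used here give a hybridisation batch.

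**Figure D1:**
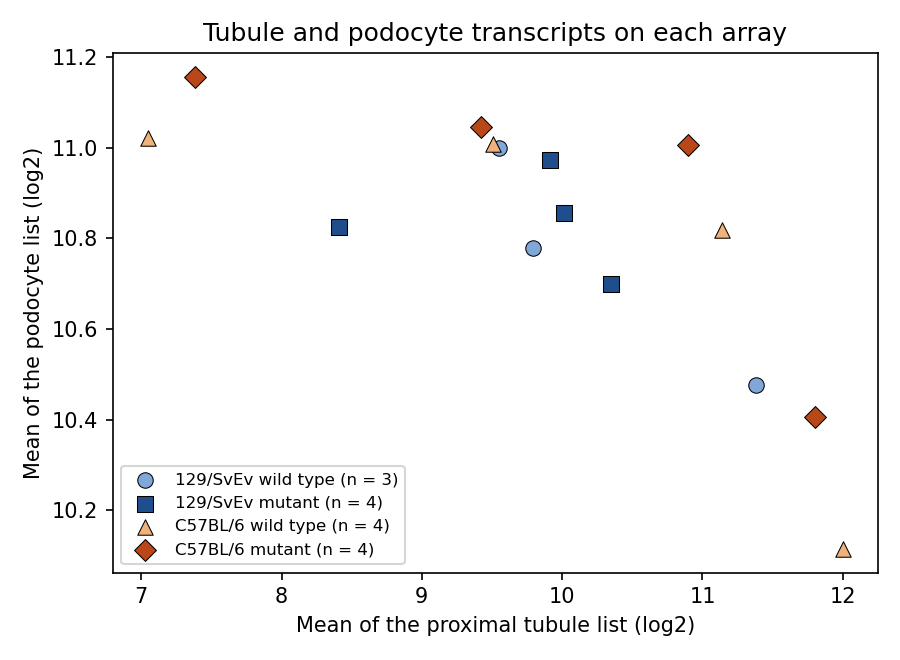
Mean log2 value of the proximal tubule list (x axis) against that of the podocyte list (y axis), 1 point per array, with colour and shape for the group. The C57BL/6 arrays span the full x range, from 7.05 to 12.0, and podocyte means are lower where tubule means are higher (r = -0.737).

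In 129/SvEv mutants, genes of macrophages and dendritic cells stood higher than other genes relative to 129/SvEv wild types: 21 of 23 measured members lay above 0, with a median log2 change of 0.23. Camera called this list and the 5 others of this paragraph at the preset correlation, but each had an adjusted p = 0.959 with an estimated correlation, and fry gave an adjusted p = 0.924. Examples were Fcgr1, an Fc receptor (0.23 ± 0.09), the lysozyme gene Lyz2 (0.69 ± 0.32) and Tyrobp, a signalling adaptor of myeloid cells (0.54 ± 0.26). Chemokines and their receptors (24 of 32 above 0, median 0.12), TNF and NF-kB targets (22 of 29, median 0.18) and matrix genes (22 of 32, median 0.15) lay on the same side. Among them were Ccl3 (0.55 ± 0.20), Ccl6 (0.76 ± 0.30), the prostaglandin synthase gene Ptgs2 (0.75 ± 0.32), the matrix gene Tnc (1.56 ± 0.44) and Col8a1 (1.20 ± 0.38). Cholesterol synthesis genes (12 of 14 below 0, median -0.14) and proximal tubule genes (16 of 19 below 0, median -0.62) were lower.

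Camera called these 6 lists with adjusted p = 2.77e-07 for macrophages, 0.00166 for chemokines and for matrix, 0.00331 for TNF and NF-kB targets, 0.0103 for cholesterol synthesis and 0.0495 for proximal tubule. Exact permutation tests of the array means gave adjusted p = 0.914 for each of them (macrophages unadjusted p = 0.114). Tnfrsf12a, the receptor of TWEAK, rose by 0.67 ± 0.15 when adjusted over the list alone (1 of 29 TNF and NF-kB targets, adjusted p = 0.0178). In the same sense the matrix gene Postn fell by 1.88 ± 0.48 (1 of 13 fibroblast genes, adjusted p = 0.0218). The fibroblast list as a whole was not called (adjusted p = 0.827). No member of the other lists passed in this comparison when adjusted over the list alone. Here and below, that adjustment does not allow for the 28 lists tested, so members of some lists may pass by chance. Leaving out 129/SvEv wild-type replicate 2 ended the calls of TNF and NF-kB targets (adjusted p = 0.148), matrix (0.253) and cholesterol synthesis (0.909) and turned that of proximal tubule genes (0.866). Calls were also lost for TNF and NF-kB targets without 129/SvEv wild-type replicate 1 (0.154), for cholesterol synthesis without 129/SvEv mutant replicate 1 (0.0703) and with the tubule covariate (0.116), and for proximal tubule genes without 129/SvEv mutant replicate 2 (0.622), C57BL/6 wild-type replicate 2 (0.0552) or C57BL/6 mutant replicate 4 (0.0613), while 15 lists were called without 129/SvEv wild-type replicate 3 and 12 without 129/SvEv mutant replicate 4.

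Over all 12393 genes limma called 0 genes in 129/SvEv (smallest adjusted p = 1), as did a linear model without moderation, and 3 with array weights. At an unadjusted p under 0.05 there were 311 genes, 197 higher and 114 lower, against 620 expected by chance, and 646 genes had groups that did not overlap (5.21%; chance gives 5.71%). The genes with the smallest p, none of them called, were Ptprv (1.02 ± 0.19), Myoz1 (0.87 ± 0.18, and 0.07 on a dimmer probe set with the tubule covariate), Ppp1r14a, Tnfrsf12a and the Wnt antagonist gene Sost (1.55 ± 0.35) among higher ones. Among lower ones they were Reln, Coch (-1.10 ± 0.25), Map3k7cl, Postn and Ibtk. With the proximal tubule mean as a covariate, limma called 2 genes, both higher in mutants. P2rx1, an ATP-gated cation channel, rose by 1.16 ± 0.16 (2.23-fold, adjusted p = 0.0329), and Ppp1r14a, an inhibitor of myosin phosphatase, rose by 0.98 ± 0.13 (1.97-fold, adjusted p = 0.0329). A dimmer probe set of P2rx1 (mean 8.41) gave 0.67 in this fit. Over all settings tried, the adjusted p of P2rx1 ran from 0.00328 to 1 and that of Ppp1r14a from 0.00272 to 1. Each kept its call in 5 of 15 fits that left out 1 array and had an adjusted p = 0.258 without 129/SvEv wild-type replicate 3. The count was 5 without 129/SvEv wild-type replicate 1 or mutant replicate 2, 1 without 129/SvEv wild-type replicate 2 or mutant replicate 1, and 0 without mutant replicate 3 or 4 or wild-type replicate 3 of 129/SvEv, C57BL/6 wild-type replicate 1 or 2, or C57BL/6 mutant replicate 1, 2 or 4.

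In C57BL/6 mutants, lymphocyte genes were lower than in C57BL/6 wild types. All 14 measured members lay below 0, with a median log2 change of -0.38, and 9 of them fell when adjusted over the list alone. They included the T cell genes Il7r (-0.71 ± 0.16) and Cd3d (-0.47 ± 0.12) and the B cell genes Cd79b (-0.89 ± 0.24) and Cxcr5 (-0.39 ± 0.09). Antigen presentation genes were lower too (14 of 15 below 0, median -0.31), with camera adjusted p = 3.08e-07 but adjusted p = 0.402 with an estimated correlation. Of these, 4 fell when adjusted over the list alone, all of MHC class II: H2-Aa (-0.79 ± 0.25), H2-Eb1 (-0.63 ± 0.22), H2-DMa (-0.46 ± 0.15) and H2-DMb2 (-0.35 ± 0.12). The lymphocyte list had camera adjusted p = 4.15e-18, adjusted p = 0.0352 with an estimated correlation, and fry adjusted p = 0.0202. With the tubule covariate its adjusted p = 0.0891 with an estimated correlation, and with 1 array left out the call with an estimated correlation held in 4 of 15 fits (highest adjusted p = 0.173, without C57BL/6 mutant replicate 4). The list mean was 5.52 ± 0.159 in mutants and 5.97 ± 0.223 in wild types (SD, n = 4 each; exact permutation p = 0.0286, the smallest that 4 against 4 can give, and adjusted p = 0.4 over 28 lists). Cell cycle genes, which were higher in mutants, had the same exact permutation p and adjusted p. Both means of the lymphocyte list lay under the log2 value of 6 used to filter dim genes.

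Camera called 13 lists in C57BL/6, 3 higher and 10 lower, and no list apart from the lymphocyte list was called with an estimated correlation or with fry. Cell cycle genes were higher (19 of 23 above 0, median 0.31, adjusted p = 1.02e-06; adjusted p = 0.557 with an estimated correlation), with Cdk1 at 0.66 ± 0.26 and Bub1 at 0.56 ± 0.25. Endoplasmic reticulum stress genes were higher (21 of 24, adjusted p = 1.92e-05; adjusted p = 0.524 with an estimated correlation), among them the chaperone gene Hspa5 (0.36 ± 0.18) and Sdf2l1 (0.59 ± 0.23). All 20 podocyte genes lay above 0 (adjusted p = 0.00239; adjusted p = 0.844 with an estimated correlation), with Nphs1, the nephrin gene, at 0.28 ± 0.27. Podocyte means were lower on arrays with more tubule transcripts (r = -0.737). The podocyte call turned direction without C57BL/6 wild-type replicate 3 (adjusted p = 0.572), the array richest in tubule transcripts, and was lost without C57BL/6 mutant replicate 1 (0.0762) or 4 (0.0729). With the tubule covariate, which could move C57BL/6 effects little as the groups' tubule means were alike, the list's median was 0.13, against 0.138 without it (camera adjusted p = 0.000811; adjusted p = 0.687 with an estimated correlation).

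Immediate early and heat shock genes, which respond to tissue handling, were lower in C57BL/6 mutants (18 of 23 below 0, adjusted p = 2.8e-05; adjusted p = 0.557 with an estimated correlation), for example Egr1 (-0.71 ± 0.27) and Junb (-0.76 ± 0.30). Chemokine genes were lower (27 of 32, adjusted p = 4.28e-05; adjusted p = 0.307 with an estimated correlation). Ccr7, a homing receptor of lymphocytes and dendritic cells, fell by 0.53 ± 0.13 when adjusted over the list alone. Lower lists also included glycolysis (adjusted p = 8.96e-05; adjusted p = 0.406 with an estimated correlation), with Pdk4 at -1.04 ± 0.34, and interferon-induced genes (adjusted p = 0.000518; adjusted p = 0.695 with an estimated correlation), with Ifit3 at -0.47 ± 0.18. Macrophage genes (19 of 23 below 0, adjusted p = 0.000518; adjusted p = 0.61 with an estimated correlation) and distal nephron genes (16 of 16 below 0, adjusted p = 0.000688; adjusted p = 0.753 with an estimated correlation) were lower. So were neutrophil (adjusted p = 0.00594; adjusted p = 0.307 with an estimated correlation) and fibroblast genes (adjusted p = 0.00669; adjusted p = 0.557 with an estimated correlation). Outside the called lists, the pericyte gene Rgs5 fell by 0.83 ± 0.20 and Igfbp3, a carrier of insulin-like growth factors, by 0.90 ± 0.18, each adjusted over its list alone. Distal nephron means were higher on arrays with more proximal tubule transcripts (r = 0.756), and their call was lost without C57BL/6 wild-type replicate 3 (adjusted p = 0.551). With the tubule covariate, which for the same reason could move it little, their median was -0.549, against -0.562 without it (camera adjusted p = 2.7e-05; adjusted p = 0.605 with an estimated correlation). Calls were also lost without C57BL/6 wild-type replicate 4 for macrophage (0.0768), interferon-induced (0.101) and neutrophil genes (0.114), without C57BL/6 wild-type replicate 1 for interferon-induced genes (0.129) and without C57BL/6 wild-type replicate 2 for fibroblast genes (0.279), while 21 lists were called without C57BL/6 wild-type replicate 3.

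Over all genes limma called 0 genes in C57BL/6 (smallest adjusted p = 0.121), as did a linear model without moderation, while array weights gave 44, 7 higher and 37 lower. At an unadjusted p under 0.05 there were 438 genes, 126 higher and 312 lower, against 620 by chance, and 223 genes had groups that did not overlap (1.8%; chance gives 2.86%). With the proximal tubule covariate 7 genes were called. Higher ones were Fxyd6, a regulator of the sodium pump (1.16 ± 0.15, 2.24-fold), Pck1, the key enzyme gene of gluconeogenesis (1.44 ± 0.19, 2.71-fold), and P2rx1 (1.08 ± 0.15, 2.11-fold), each with adjusted p = 0.0192, and Tnfrsf19 (1.36 ± 0.22, adjusted p = 0.0406). Lower ones were the granzyme gene Gzmb (-0.83 ± 0.13), Vps13c (-0.57 ± 0.09) and the tubulin gene Tuba8 (-0.55 ± 0.09), each with adjusted p = 0.0406. Gzmb and Vps13c lay near the floor (means 4.86 and 4.98), and Tuba8 was dim too (mean 5.34). Dimmer probe sets of the same genes gave 0.14 and 0.03 for Tnfrsf19 (means 5.42 and 5.42), -0.08 for Pck1 (mean 3.87) and 0.93 for P2rx1 (mean 8.41) in this fit. Pck1 is itself a member of the proximal tubule list, and without the covariate its SE was 1.21. Over all settings tried, the adjusted p of Fxyd6 ran from 0.000613 to 0.776, of Pck1 from 0.00942 to 1, of P2rx1 from 0.0135 to 1, of Tnfrsf19 from 0.0406 to 1, of Gzmb from 0.0226 to 0.776, of Vps13c from 0.0226 to 0.872 and of Tuba8 from 0.00525 to 0.776. Leaving out 1 array kept the call of Fxyd6 in 12 of 15 fits, Pck1 in 11, P2rx1 in 10, Tuba8 in 4, Gzmb and Vps13c in 3 and Tnfrsf19 in 2. The count of covariate calls was 0 without C57BL/6 wild-type replicate 1, 0 without C57BL/6 mutant replicate 1, 1 without C57BL/6 wild-type replicate 4 and 14 without C57BL/6 wild-type replicate 3. It was 4 without 129/SvEv wild-type replicate 1, and 3 without mutant replicate 1, 3 or 4 or wild-type replicate 3 of 129/SvEv, or C57BL/6 mutant replicate 2, 3 or 4.

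**Figure D2:**
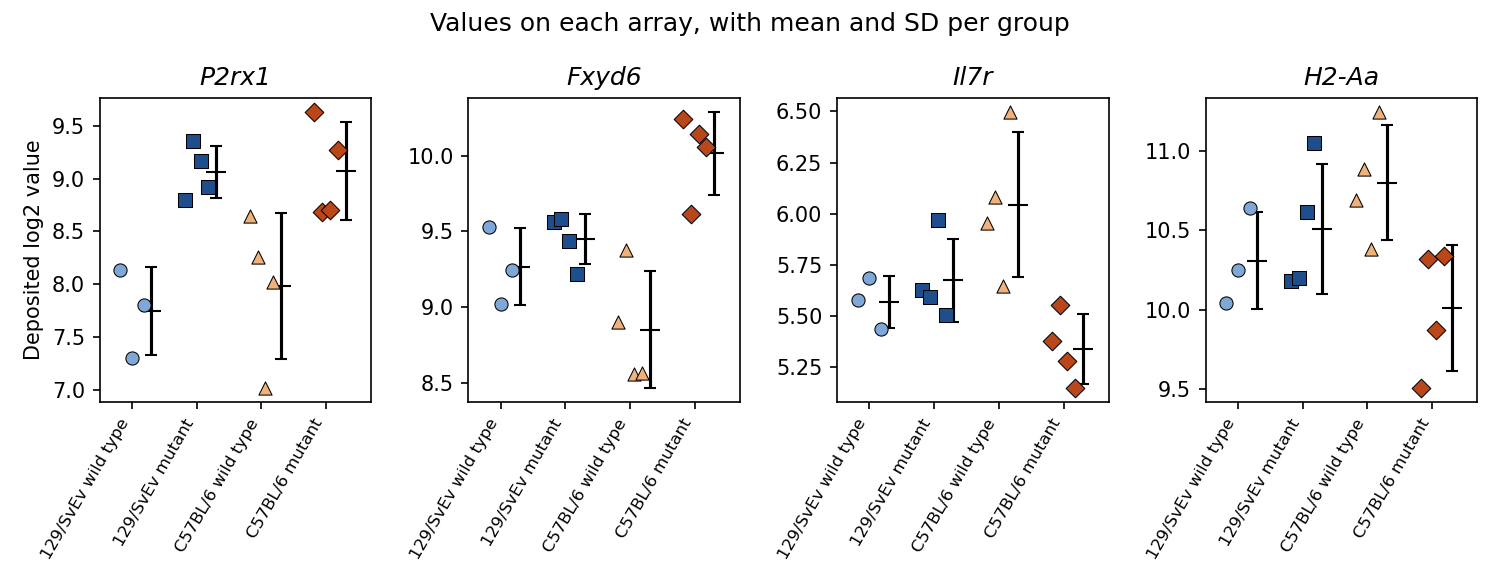
Deposited log2 values (y axis) of P2rx1, Fxyd6, Il7r and H2-Aa on each array, by group, with the group mean and SD beside the points. P2rx1 is higher in the mutants of both strains, Fxyd6 is higher in C57BL/6 mutants, and Il7r and H2-Aa lie lower in C57BL/6 mutants (-0.71 and -0.79).

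The mutant effects of the strains, taken as the 129/SvEv effect minus the C57BL/6 effect, differed by camera at the preset correlation for macrophage, lymphocyte, chemokine and antigen presentation genes, but not for interferon-induced (adjusted p = 0.14) or complement genes (0.0981). With an estimated correlation the adjusted p was 0.248 for macrophage, 0.123 for lymphocyte, 0.123 for chemokine and 0.248 for antigen presentation genes, and neither this test nor fry called a list for the difference. Macrophage and dendritic cell genes had a median difference of 0.38, with 22 of 23 members above 0, among them Tyrobp (1.05 ± 0.36) and Csf1r, the receptor of macrophage colony-stimulating factor (0.67 ± 0.26). Chemokine genes had 28 of 32 members above 0, with Ccl3 at 1.01 ± 0.27 and Ccl6 at 1.48 ± 0.41. Antigen presentation genes had 15 of 15 above 0 and a median of 0.32, with H2-Aa at 0.99 ± 0.36. Lymphocyte genes had 12 of 14 above 0. Of these, Il7r (0.81 ± 0.23) and Cd3d (0.55 ± 0.17) passed when adjusted over the list alone, as did Igfbp3 (1.04 ± 0.26) in the growth factor list.

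Camera called 12 lists for this difference, 10 above 0 and 2 below. The smallest adjusted p-values were 1.13e-11 for macrophages, 3.1e-10 for lymphocytes, 1.3e-09 for chemokines and 1.47e-08 for antigen presentation. TNF and NF-kB targets, glycolysis, immediate early, neutrophil, matrix and fibroblast genes also lay above 0. Cholesterol synthesis and cell cycle genes lay below 0. Limma called 0 genes for the difference (smallest adjusted p = 0.999) and 1 with array weights. At an unadjusted p under 0.05 there were 243 genes, 199 above and 44 below 0, against 620 by chance; a linear model without moderation called 0. In fits that left out 1 array, calls ended for matrix genes in 7 of 15 (highest adjusted p = 0.49, without 129/SvEv wild-type replicate 2) and with the tubule covariate (0.129), for fibroblast genes in 8 (0.432, the same array) and for immediate early genes in 4 (0.615, without 129/SvEv mutant replicate 1). They ended for cell cycle genes in 3 (0.754, without 129/SvEv wild-type replicate 3), and in 1 each for cholesterol synthesis (0.333, without 129/SvEv wild-type replicate 2), glycolysis (0.0585, without 129/SvEv wild-type replicate 1) and neutrophil genes (0.0958, without C57BL/6 wild-type replicate 4), while 20 lists were called without C57BL/6 wild-type replicate 3. Smallest p-values belonged to Tuba8 (0.73 ± 0.14) and the killer cell gene Nkg7 (0.68 ± 0.15) above 0 and Fxyd6 (-0.98 ± 0.28) below 0. Tuba8 and Nkg7 lay under the log2 value of 6 used to filter dim genes (means 5.34 and 5.83).

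**Figure D3:**
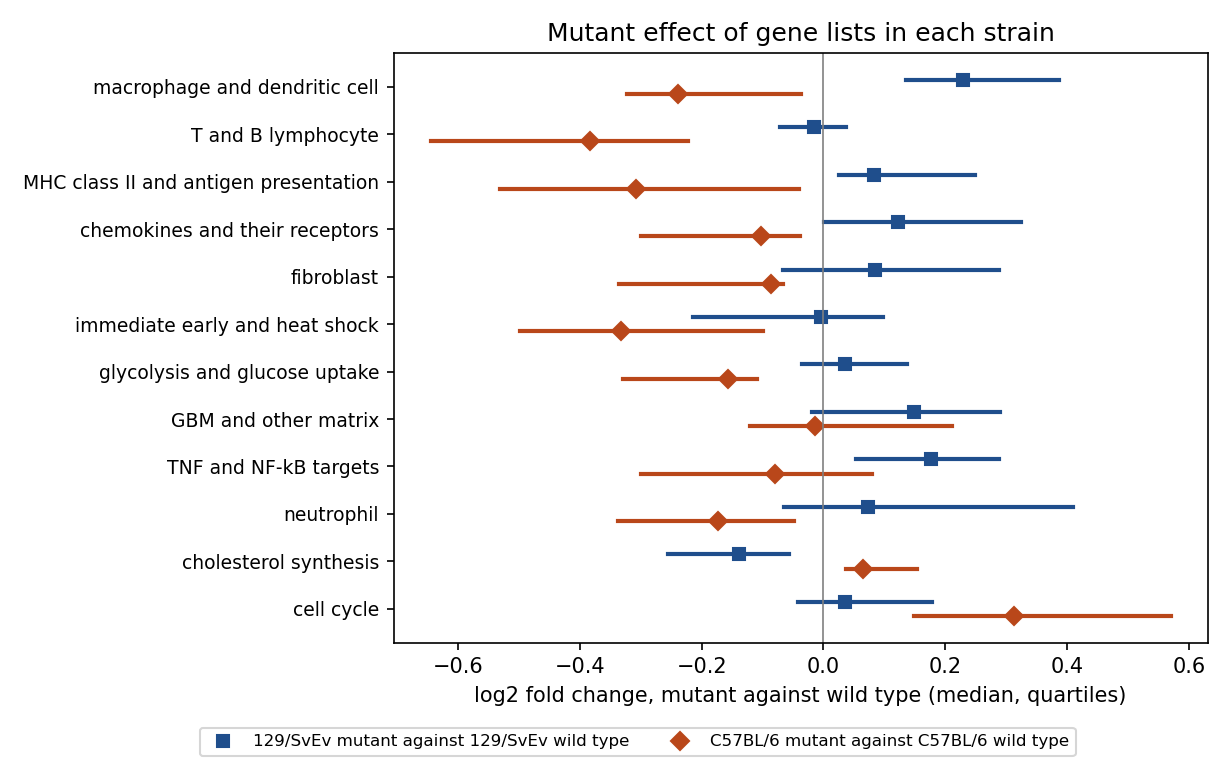
Median (point) and quartiles (line) over list genes of the log2 fold change of mutants against wild types in each strain (x axis), for the 12 lists called for the difference between strains (y axis). Macrophage genes have a median of 0.23 in 129/SvEv and -0.24 in C57BL/6, and lymphocyte genes of -0.02 and -0.38.

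The remaining lists were called in neither strain nor for the difference between them in the fit without covariates. With the tubule covariate, camera called complement in 129/SvEv (adjusted p = 0.0119) and for the difference (0.0184), and oxidative stress and NRF2 targets in 129/SvEv (0.00483) and for the difference (0.0164), all above 0. With an estimated correlation these had adjusted p = 0.762, 0.381, 0.762 and 0.552. The covariate also brought calls for the difference for podocyte (0.0181, below 0) and distal nephron genes (0.000416, above 0), with adjusted p = 0.756 and 0.622 at an estimated correlation. In 129/SvEv and C57BL/6 their camera adjusted p-values were 0.0812 and 0.996 for complement, 0.0812 and 0.877 for TGF-beta and profibrotic genes, 0.328 and 0.527 for oxidative stress and NRF2 targets, 0.52 and 0.996 for gluconeogenesis and fatty acid oxidation, and 0.16 and 0.778 for oxidative phosphorylation. They were 0.618 and 0.371 for angiogenic and growth factors, 0.0997 and 0.996 for mesangial cells and pericytes, 0.827 and 0.876 for endothelial cells, 0.366 and 0.393 for parietal cells, 0.995 and 0.941 for juxtaglomerular and renin-angiotensin genes, and 0.995 and 0.859 for red blood cells. Median and mean, or these and the test, had opposite signs in 129/SvEv for endothelial (median -0.01, mean 0.03), fibroblast (0.09, -0.03), red blood cell (0.02, -0.08) and oxidative stress genes (-0.0094, 0.02), and juxtaglomerular genes had a median of 0.01 with a test direction below 0. In C57BL/6 they did so for matrix (-0.01, 0.02), endothelial (0.03, -0.0076), TGF-beta (0.0099, -0.03), oxidative stress (-0.05, 0.0035) and gluconeogenesis genes (-0.0059, 0.08), and for the difference for endothelial (-0.03, 0.04) and juxtaglomerular genes (-0.02, 0.02), with parietal genes at a median of 0.01 and a test direction below 0. Ins2, the gene that carries the Akita allele, had log2 changes of -0.08 ± 0.14 in 129/SvEv and -0.04 ± 0.13 in C57BL/6. It is an islet gene, so its level in kidney says nothing of the labels. Of the 12 measured genes chosen for diabetic kidney disease, limma called 0 in either strain, and the smallest unadjusted p-values were 0.138 and 0.253.

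Across genes, which are not independent replicates, the mutant effects of the strains, which share no arrays, correlated at r = 0.338 (Spearman 0.237). At an unadjusted p under 0.05 in both strains, 19 genes were higher in both and 18 lower in both, where 2 and 2.87 were expected from independent lists, and 5 went opposite ways (Fisher's exact test, two-sided, p = 1e-13 for higher and 4.56e-10 for lower genes). That test takes genes as independent, so its p-values do not measure the spread between arrays. Overlap of called genes could not be tested with 0 called. The correlation was 0.0341 without 129/SvEv wild-type replicate 2, 0.0293 without C57BL/6 mutant replicate 1 and -0.0698 without C57BL/6 wild-type replicate 3.

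The strain comparisons in wild types and in mutants restate the difference of the mutant effects. As the values of the strains averaged over genotypes were nearly equal, a list that is higher in 1 genotype is lower in the other by that alone. In wild types, 129/SvEv arrays had lower macrophage (22 of 23 below 0), lymphocyte (12 of 14), antigen presentation (15 of 15) and chemokine genes (26 of 32) than C57BL/6 arrays. Camera adjusted p-values were 3.9e-10, 3.9e-10, 1.17e-09 and 6.89e-08, and 0.222, 0.129, 0.222 and 0.129 as adjusted p with an estimated correlation. In mutants the same lists were higher in 129/SvEv (21 of 23, 13 of 14, 12 of 15 and 26 of 32 above 0). Camera adjusted p-values were 7.85e-10, 8.48e-08, 1.66e-05 and 1.63e-08, and 0.32, 0.275, 0.419 and 0.182 as adjusted p with an estimated correlation. Camera called 14 lists in wild types, 9 without C57BL/6 wild-type replicate 2, and 11 in mutants. Limma called 0 genes in each (smallest adjusted p = 1), as did a linear model without moderation, with 48 and 66 genes at an unadjusted p under 0.05 against 620 by chance. Groups did not overlap for 127 genes in wild types (1.02%; chance gives 5.71%) and 78 in mutants (0.629%; chance gives 2.86%). Smallest p-values belonged to Nkg7 in wild types (-0.40 ± 0.11) and Tuba8 in mutants (0.45 ± 0.09).

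Averaged over genotypes, 129/SvEv and C57BL/6 arrays had nearly equal values. In a limma fit of strain and genotype without their interaction, the strain average had an unadjusted p under 0.1 for 6 of 12393 genes, where chance gives 1239, and 91.4% of genes had a p above 0.5. Its SD over genes was 0.0521, against 0.185 and 0.173 for the mutant effects in 129/SvEv and C57BL/6. With averages this close, the strain differences above add little to the difference of the mutant effects.

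**Figure D4:**
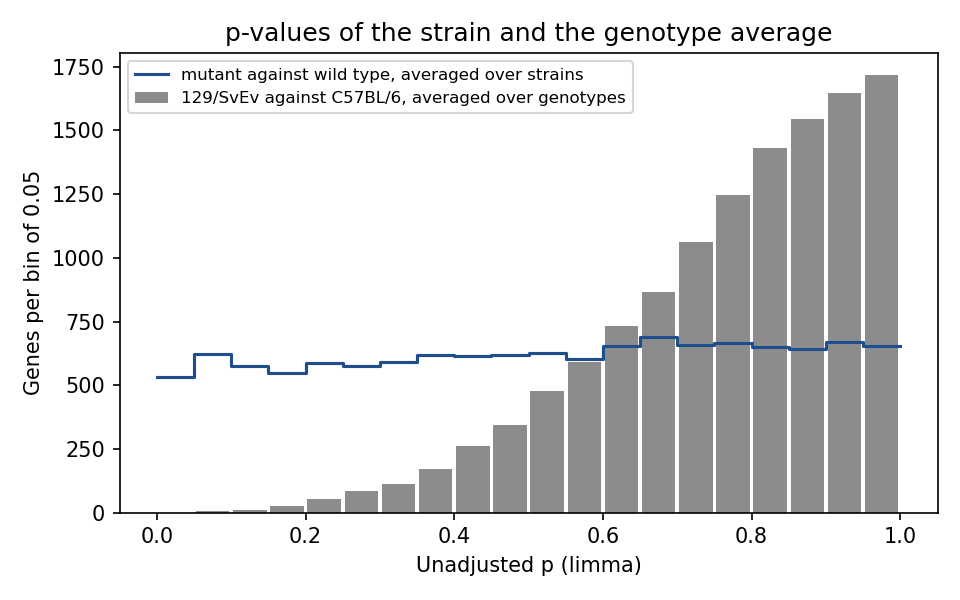
Number of genes (y axis) per bin of the unadjusted limma p-value (x axis), for the strain difference averaged over genotypes (bars) and the mutant effect averaged over strains (line), both from the fit without an interaction. The strain average has 0 genes under 0.05 and 1718 in the last bin, while the genotype average has 534 and 655.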

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

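The tests of the lymphocyte pattern and the fits of lists with 1 array left out were chosen after the results were seen.

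Array means of the lists stood apart in 3 of 84 groups of 4 arrays, and chance flags about 1 in 20 groups, here 4.2. The gap to the nearest array, divided by the group's range, was 0.983 for cholesterol synthesis in 129/SvEv mutants, where replicate 1 was lowest (8.09, others 8.24 to 8.24). It was 0.842 for matrix genes in C57BL/6 wild types, where replicate 3 was lowest (8.68, others 9.30 to 9.41), and 0.875 for endothelial genes in C57BL/6 mutants, where replicate 4 was highest (10.9, others 10.4 to 10.4).

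Mutant effects differed between the strains for 12 lists by the camera test of the difference itself at the preset correlation. None was called with an estimated correlation, where adjusted p-values ran from 0.123 to 0.816. At the preset correlation, adjusted p-values were 1.13e-11 for macrophage and dendritic cell genes, 3.1e-10 for lymphocyte, 1.3e-09 for chemokine, 1.47e-08 for antigen presentation, 0.000239 for TNF and NF-kB, 0.000468 for glycolysis, 0.000731 for cholesterol synthesis and 0.00119 for cell cycle genes. They were 0.0119 for neutrophil and for immediate early genes, 0.0154 for matrix and 0.0299 for fibroblast genes. The calls of macrophage, lymphocyte, chemokine, antigen presentation and TNF and NF-kB genes held in all 15 fits with 1 array left out, and the other 7 did not. Some lists share genes with other lists, so these calls are not fully separate. Shared were 7 of 13 fibroblast, 7 of 32 chemokine, 6 of 29 TNF and NF-kB, 6 of 32 matrix and 5 of 23 macrophage genes, and 0 lymphocyte genes.

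The lymphocyte list was lower in C57BL/6 mutants with any 1 array left out, its least negative median being -0.328, which argues against a single array as the source, although the call with an estimated correlation held in 4 of 15 such fits (adjusted p = 0.173 without C57BL/6 mutant replicate 4). The proximal tubule means of the C57BL/6 groups differed by -0.0465, for which the slope of the list mean on them (0.0137 ± 0.0295, SE) gives a shift of at most 0.00339 with 2 SE, against a median of -0.384, which argues against proximal tubule cells; with the covariate the adjusted p with an estimated correlation moved from 0.0352 to 0.0891. In that fit distal nephron genes (median -0.549, 16 of 16 below 0) and immediate early and heat shock genes (median -0.332) were also lower by camera (adjusted p = 2.7e-05 and 2.92e-05, and 0.605 for each with an estimated correlation). C57BL/6 wild types spanned distal nephron means from 8.68 to 11.2, around those of mutants (9.14 to 9.92). Their lymphocyte means nevertheless lay above those of mutants (5.75 to 6.28 against 5.36 to 5.74). Among wild types, replicate 1 was lowest in distal genes and had a lymphocyte mean of 5.92, and replicate 3 was highest and had 5.75. This argues against distal tubule cells as the source of the lower lymphocyte list, for which handling stays open. Blood or lymphoid cells carried over in different amounts may account for it. The red blood cell list of 4 genes, 1 of them shared with the distal nephron list, differed by -0.275 (SE 0.186), too imprecise to decide. Its gene Hba-a1 lay near the floor (mean 4.92). The lymphocyte list was dim as well. Its brightest gene, Cd3e, had a mean of 7.27, but the C57BL/6 array means of the list lay between 5.36 and 6.28. Some list members lie within 20 Mb of Apoa1: leaving the list out lowered the genes of that window from 255 to 251. Those at an unadjusted p under 0.05 in C57BL/6, without the covariate, went from 16 to 13. Donor DNA near Apoa1, raised below for Fxyd6, may thus bear on these members, which was not tested. Fewer lymphocytes in the glomeruli of C57BL/6 mutants stays an open biological explanation, untested here.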

How the results depend on the processing

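Tests with arrays left out of list tests, of covariate fits, of the correlation of effects and of the averaged effect, the covariate in that correlation, the block together with the covariate and the removal of far arrays were chosen after the results were seen. Limma called 0 genes in all 5 comparisons under every alternative except the following. Array weights gave 3 genes in 129/SvEv (Myoz1, Ptprv and Postn), 44 in C57BL/6 (4 of them lymphocyte genes, and 5 also called with the covariate) and 1 for the difference (Tuba8). The weights ran from 0.212 for C57BL/6 wild-type replicate 3 to 4.96 for C57BL/6 wild-type replicate 2; the cause was not tested. The proximal tubule covariate gave 2 and 7 genes. Leaving out 1 array gave 0 to 1 in 129/SvEv (1 without mutant replicate 2) and 0 to 2 in C57BL/6 (2 without wild-type replicate 2). With the covariate, these ranges were 0 to 5 (5 without 129/SvEv mutant replicate 2) and 0 to 14 (14 without C57BL/6 wild-type replicate 3, 0 without C57BL/6 wild-type replicate 1). The cause was not tested.

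Estimated correlations left 0 called lists in 129/SvEv, 1 in C57BL/6 and 0 for the difference and both strain comparisons, and fry left 0, 1, 0, 0 and 0; both allow for genes of a list moving together. Leaving out 1 array gave 5 to 15 called lists in 129/SvEv (15 without wild-type replicate 3), 10 to 21 in C57BL/6 and 10 to 20 for the difference (both highest without C57BL/6 wild-type replicate 3), and 9 to 20 in wild types (9 without C57BL/6 wild-type replicate 2). Removing the arrays of highest and lowest tubule content in each C57BL/6 group gave 0 called genes and 15 to 17 lists in the comparisons with C57BL/6 arrays. The proximal tubule list in 129/SvEv turned direction under the covariate (adjusted p = 0.879), which is made of that list, and ranged from 0.00379 to 0.866 with 1 array left out, turning without wild-type replicate 2 (0.866). The podocyte list in C57BL/6 ranged from 7.75e-07 to 0.572, turning without wild-type replicate 3 (0.572). Ins2 ranged from -0.16 to 0.041 in 129/SvEv and from -0.14 to 0.0067 in C57BL/6. Values of the other genes chosen for diabetic kidney disease are not given singly; of the 12, 7 changed sign under some alternative in 129/SvEv, 6 in C57BL/6 and 6 for the difference. Of the lists called in the strain comparisons, 6 of 14 and 1 of 11 did so.

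The correlation of the strains' effects was 0.383 in the upper 50% of genes, 0.327 with the mean of probe sets and 0.243 with the covariate, but ran from -0.0698 to 0.516 with 1 array left out (jackknife SE 0.625), so its sign rests on single arrays. Renormalizing moved no median of all genes by over 0.1, but array medians already lay close together, so this outcome was set in advance. It says nothing of single genes or lists. With the replicate number as a block, limma called 0 genes in each comparison, and with block and covariate together 0 in both strains and for the difference. Deviations of equally numbered arrays correlated between -0.733 and 0.822, and 1 of 6 arrays in 129/SvEv and 3 of 8 in C57BL/6 correlated best with their own number. No pairing by number was thus apparent, but tubule content weighs on such deviations, so pairing cannot be excluded. For the effect averaged over strains, the block with the covariate gave 3 genes against 9, omitting the covariate gave 0, and leaving out 1 array gave 2 (without C57BL/6 wild-type replicate 1) to 22 (without 129/SvEv wild-type replicate 1).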

Other observations

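The averaged mutant effect, all splits with the tubule covariate, the tests of the strain averages and those of neighbouring genes at an unadjusted p were chosen after the results were seen; the splits of the 5 comparisons without it, the tests of tubule cells and the tests of called genes near Ins2 and Apoa1 were not.

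Averaged over both strains and with the tubule covariate, limma called 9 genes, 8 higher and 1 lower in mutants; without the covariate the fit of the 4 group means called 0, with 514 genes at an unadjusted p under 0.05. P2rx1 was higher by 1.12 ± 0.11 (SE, 2.17-fold, adjusted p = 0.00112) and Pck1 by 1.31 ± 0.14 (2.49-fold, adjusted p = 0.00176), and both were called in all 15 fits with 1 array left out. Tnnt2, the cardiac troponin T gene (1.24 ± 0.16), and Sost (1.20 ± 0.16) were called in 14, Ppp1r14a (0.66 ± 0.09) and Endou (0.62 ± 0.09) in 13, the glutathione transferase gene Gsta2 (1.15 ± 0.17) and Tnfrsf19 (1.05 ± 0.16) in 8, and Reln (-0.39 ± 0.06) in 2. The difference between strains passed for none of the 9 (limma, smallest adjusted p = 0.998). Camera called 9 lists at the preset correlation, 4 higher (endoplasmic reticulum stress, adjusted p = 0.000893; cell cycle, 0.00492; podocyte and matrix, 0.0481 each) and 5 lower (lymphocyte, 3.45e-08; interferon-induced and immediate early, 0.000893 each; distal nephron, 0.023; antigen presentation, 0.0493). None was called with an estimated correlation, the smallest adjusted p being 0.469 for lymphocytes. Dimmer probe sets of the same genes gave less with the covariate for Sost (0.47 in 129/SvEv and 0.53 in C57BL/6) and Tnfrsf19 (0.03 to 0.14). In 129/SvEv and C57BL/6 they gave 0.67 and 0.93 for P2rx1, 1.01 and 0.96 for Tnnt2, and 0.18 and -0.08 for Pck1 (mean 3.87). Reln (mean 5.31) and Tnnt2 (mean 5.75, and 4.63 on its dimmer probe set) lay under the log2 value of 6 used to filter dim genes. Pck1 is itself a member of the proximal tubule list. Without the covariate its averaged effect was 0.96 ± 0.89 and that of Gsta2 was 0.85 ± 0.78. Of 100 drawn splits within strain, 3 gave at least 9 genes, the real split included. This share of 0.03 lies under 0.05, but its 95% interval (exact Clopper-Pearson) runs from 0.00623 to 0.0852, so chance is not firmly excluded. The highest other split gave 252 genes and parted the arrays of neither strain by tubule content. A further structure of the samples is possible, but the cause of this count was not tested. Leaving out 1 array gave 22 genes without 129/SvEv wild-type replicate 1, 5 without 129/SvEv wild-type replicate 3 and 2 without C57BL/6 wild-type replicate 1.

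Splits of the same arrays gave the following for single comparisons. With 0 genes called, as many are given by any split (35 in 129/SvEv, 35 in C57BL/6, 100 drawn for the difference, 35 in wild types and 35 in mutants), so these counts say nothing of chance. The highest others gave 1, 1819, 499, 846 and 0 genes. The split with 1819 set the 4 C57BL/6 arrays with the lowest proximal tubule means against the 4 with the highest, that with 846 parted the wild-type arrays in the same way, and that with 499 did so for the C57BL/6 arrays but not fully for the 129/SvEv arrays, which points to tubule content as a structure of these samples. With the covariate, 3 of 35 splits in 129/SvEv gave at least the real 2 genes (highest other 2) and 4 of 35 in C57BL/6 gave at least the real 7 (highest other 344, with the 4 arrays farthest out in tubule content on the same side), so chance cannot be excluded for either. Whether tubule cells in the preparation shaped the genes called could not be tested, as 0 and 0 genes were called without the covariate. The tests of called genes near Ins2 in 129/SvEv and near Apoa1 in C57BL/6 could not decide on donor DNA there, as 0 and 0 genes were called without the covariate. At an unadjusted p, genes within 20 Mb of Ins2 had odds ratios from 0 to 0.599 in 129/SvEv (8 of 32 window tests, Fisher's exact p from 0.183 to 0.628), with no excess in any.

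The near equality of the strain averages is unusual for inbred strains. Equal expression in values that had not been adjusted, with arrays exchangeable within genotype, is argued against: among 2450 splits of the arrays within genotype, the real split ranked 1 from the lowest in the SD over genes (0.0521, lowest other 0.0637, median 0.136), and 2 with each gene's trend with tubule content removed (0.0492, lowest other 0.0461, median 0.0963), as splits differ in that content. A structure other than tubule content that was balanced between the strains would also lower this rank. An adjustment of the values for strain, or for a batch that followed strain, before deposit is a candidate explanation that stays untested: that 91.4% of genes (86.9% with the covariate) had a p above 0.5 for the strain average is the pattern itself, and the sources used here describe no such step. If a constant shift per strain had been removed, the mutant effects within each strain and their SE would be as they are, while strain differences in level would be lost. If a batch that crossed the groups had been removed, the residual degrees of freedom would be overstated and the printed SE and p-values too small.

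Fxyd6, which was higher in C57BL/6 mutants, is a neighbour of Apoa1 in GRCm38.p6, with 18 genes between them. If the renin transgene lay at the Apoa1 locus, which is not given in the sources used here, DNA carried along with it may account for the level of Fxyd6. Genes within 20 Mb of Apoa1 passed an unadjusted p under 0.05 with an odds ratio of 1.47 (Fisher's exact p = 0.102) with the covariate and without lymphocyte genes, and 1.66 (p = 0.031) with them. These were among 32 window tests, 8 of them of Apoa1 in C57BL/6, where odds ratios ran from 1.47 to 2.47 and Fisher's exact p from 0.015 to 0.456. Fxyd6 itself was counted in that window. Genes near Ins2 in C57BL/6 had odds ratios from 0.917 to 1.65, and genes near Apoa1 in 129/SvEv from 0 to 0.786. The question of donor DNA near Apoa1 thus stays undecided. A response of Fxyd6 to diabetes or hypertension in C57BL/6 stays open, and its difference from 129/SvEv did not pass (adjusted p = 0.999).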
